A study of Homo sapiens with 6 samples.

How the data were processed

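RNA-seq libraries of THP-1 cells were grouped by the treatment label and description of each sample into control (n = 3) and pristimerin (n = 3). Per the labels' protocols, RNA was extracted with TRIzol, poly(A)-selected, made into strand-specific dUTP libraries and sequenced as paired-end reads on Illumina instruments. The submitters' processing notes name the genome build hg38; the aligner, the counting tool, their versions and whether counting used the strand are not given in the sources used here. If counting ignored the strand, reads of a gene and an overlapping antisense gene were mixed, and 26 of the 112 genes named or examined by the rule below overlap another gene that has at least 20% of their CPM (19 on the opposite strand, 8 on the same strand).

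The 3 deposited tables hold, for 25336 genes with Ensembl identifiers, coordinates and biotype, whole-number counts and FPKM values. The deposited counts are unnormalised, one column per library. The deposited FPKM values are proportional to the count divided by a fixed gene length and by the column total of the counts: over 4308 genes with at least 1000 counts, the length implied by both tables varied between libraries by a coefficient of variation of at most 2.14e-05. The table that combines both units repeated the same counts and FPKM values. The table lists 16205 protein-coding genes, 9115 long non-coding RNA genes, 13 genes marked artifact and 3 ribozyme genes. Gene starts equalled those of GENCODE release 29 for 14832 of 23215 shared identifiers, and were one base lower for 340, so coordinates are taken as 1-based on hg38. Of 1002 list entries, 967 were matched to a gene of the table.

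Totals per library ranged from 19057219 to 30568593 counts, so that 3 counts correspond to between 0.0981 and 0.157 CPM. Chi-square tests of counts between replicates of a group gave 2.6 to 10.6 per degree of freedom, so no library repeats another. The labels call the samples replicate biosamples and do not say whether they were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels give no batch or date, so no named batch could be examined. The first principal component held 56.7% of the variance of log2 CPM and separated the groups. The second held 13.1% and set replicate 2 of control (-14.02) and of pristimerin (-20.28) apart from the other libraries (2.55 to 13.04).

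Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM scaling, and the quasi-likelihood F test with group as the only term. The Benjamini-Hochberg adjusted p threshold was 0.05, and 2-fold calls also needed an absolute log2 fold change of at least 1. The filter kept 15305 genes and left out 10031. TMM factors lay between 0.9702 and 1.0311. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values given by group are scaled by TMM, except those of long non-coding RNA genes and summed cell-type markers. These, and mean CPM values over the 6 libraries, are relative to the plain library totals. Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, for the 30 of 32 lists with at least 5 tested members. Camera was repeated with the correlation estimated from the libraries, and fry was run on the same lists. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Shares of counts were compared by exact two-sided permutation tests (scipy 1.17.1). Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.

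The tests, the gene lists, the alternatives and the naming rule were fixed before the data were examined. The rule names ATF3 and SLC7A11, then the 10 largest increases and the 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 CPM, no overlap between the groups and a symbol that is not a clone or locus name, then, for each list described, its fixed anchor genes and up to 3 further called members with the largest absolute log2 fold change and a mean of at least 5 CPM. The lists described gene by gene are the 16 called by camera and 4 others (integrated stress response, iron handling, NF-kappaB and interferon), and this choice was made after seeing the data. Some genes the rule selects are not reported here. Genes outside the rule are said to be named after their values were seen.

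The alternatives were DESeq2 size factors, upper-quartile scaling and library totals in place of TMM; no low-count filter; a mean of at least 5 CPM; DESeq2 1.42.0; limma-voom; limma with a trend on log2(FPKM + 1) and log2(FPKM + 0.1), for genes with a mean FPKM of at least 0.1; the replicate number as a block; protein-coding genes alone; and leaving out each library in turn. Cyclic loess normalization, lists without shared members and a few further settings were added after seeing the data. The steps were tested on simulated counts for the 15305 genes of the pristimerin and control comparison, with 200 genes changed. EdgeR recovered 79 of 100 genes changed 1.5-fold and 97 of 100 changed 2-fold and called 12 of 14860 unchanged genes, DESeq2 recovered 74 and 92 and called 11, and limma-voom recovered 77 and 97 and called 12. A simulated list of 30 genes raised by 0.3 on the log2 scale was called by camera and by fry, which called 0 and 1 of 50 unchanged lists. The simulated genes varied independently of each other. This run therefore does not test the preset correlation for lists whose genes vary together. It also changed far fewer genes than the 4529 called in the data, and planted no trend of fold change with abundance. Scaling and error rate under such conditions were not tested.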

Results

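RNA was sequenced from THP-1 cells, an established human line of monocytic acute myeloid leukaemia, in 3 libraries labelled control and 3 libraries labelled pristimerin. Pristimerin is a quinone-methide triterpenoid from plants of the bittersweet family. The series title concerns erastin-induced ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, and names the transcription factor ATF3 and the cystine transporter subunit SLC7A11. None of the 6 libraries carries an erastin label, so the comparison made here is the one between libraries labelled pristimerin and control. The labels do not say whether any of the cells also received erastin. The labels give no dose and no exposure time. The count table held 25336 genes, and its totals per library were 26574679, 27880414 and 19057219 counts for control replicates 1, 2 and 3 and 30568593, 26594567 and 24323627 for pristimerin replicates 1, 2 and 3. Higher and lower below always refer to the libraries labelled pristimerin relative to those labelled control.

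Both genes of the title were lower in the libraries labelled pristimerin. SLC7A11, which imports cystine for glutathione synthesis (ENSG00000151012, protein-coding, hg38 chromosome 4, 138164097 to 138242349, minus strand), measured 14.98 ± 1.28 CPM (the count relative to the TMM-scaled library total; SD, n = 3) in control and 4.69 ± 0.34 (SD, n = 3) in pristimerin libraries, a log2 fold change of -1.68 (SE 0.11), with an adjusted p of 7.9e-09 in edgeR's quasi-likelihood test. The control libraries held 13.5, 15.63 and 15.8 CPM of SLC7A11 and the pristimerin libraries 4.30, 4.87 and 4.92. ATF3, a stress-induced transcription factor of the CREB family (ENSG00000162772, protein-coding, hg38 chromosome 1, 212565334 to 212620777, plus strand), measured 1.93 ± 0.35 CPM (SD, n = 3) against 0.322 ± 0.095 (SD, n = 3), a log2 fold change of -2.54 (SE 0.31), with an adjusted p of 1.2e-05 in edgeR's test. ATF3 was weakly expressed: its values rested on 57, 44 and 42 counts in the control libraries and on 11, 10 and 5 counts in the pristimerin libraries. On the log2(FPKM + 1) scale, where the pseudocount outweighs low values, the differences shrank to -0.81 for SLC7A11 and -0.47 for ATF3, both still past the threshold in limma's test.

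**Figure D1:**
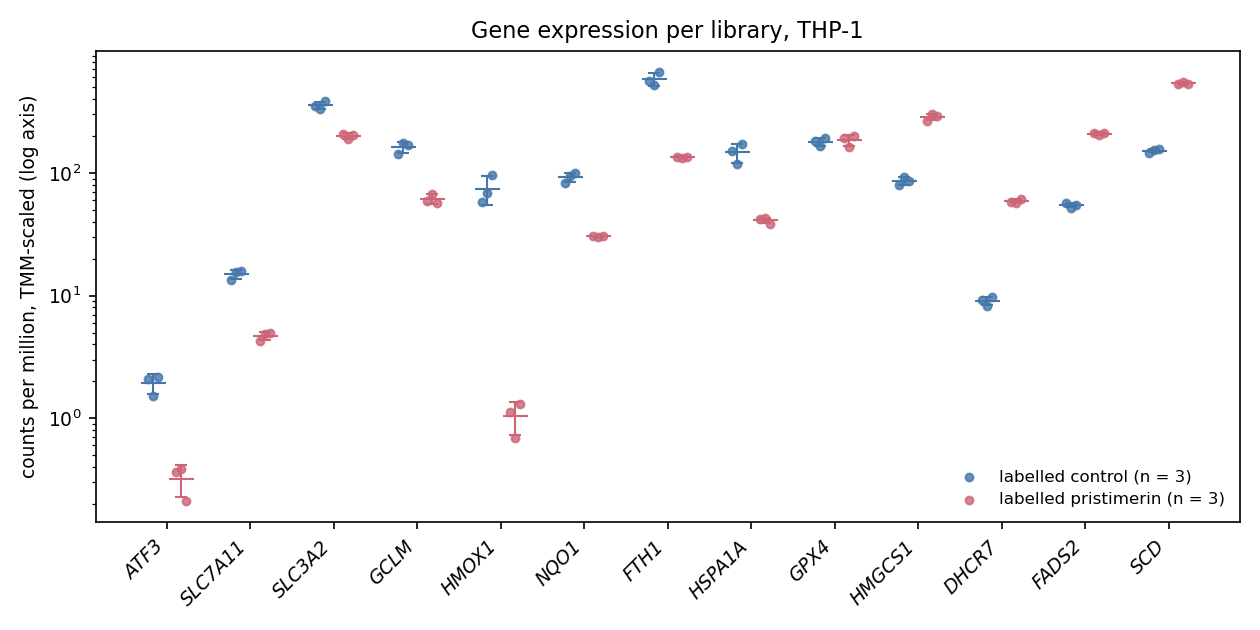
TMM-scaled CPM (log axis) of 13 genes in each library, with points for the 3 libraries labelled control and the 3 labelled pristimerin and bars for the mean and SD. SLC7A11 lies between 13.5 and 15.8 in control and between 4.30 and 4.92 in pristimerin libraries, HMOX1 falls from a mean of 74.3 to 1.05, HMGCS1 rises from 86.5 to 286.0, and the groups of GPX4 overlap.

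Of 15305 genes tested, 2216 were higher and 2313 lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test, so that 48.9% of the calls were increases. Camera called 9 of 30 gene lists higher and 7 lower, and 1 and 0 with an estimated correlation. At least 2-fold changes were seen in 139 genes higher and 391 lower, an excess of decreases that was absent among genes with a mean of at least 5 CPM (63 and 66) and turned on log2(FPKM + 1) (47 and 40) and with cyclic loess normalization, chosen after seeing the data (231 and 196), but stayed on log2(FPKM + 0.1) (110 and 322). The 10 largest increases under the naming rule were IL31RA (log2 fold change 2.84), the sterol enzyme DHCR7 (2.70), MYOF (2.65), the ectoenzyme CD38 (2.32), the sterol enzyme MSMO1 (2.27), the fatty acid desaturase FADS2 (1.93), the NF-kappaB inhibitor TNFAIP3 (1.87), the desaturase SCD (1.82), the sterol sensor INSIG1 (1.79) and FAM111B (1.75), each with an SE of at most 0.12. The 10 largest decreases were the haem oxygenase HMOX1 (-6.14), the chaperone CLU (-5.62), OSGIN1 (-2.83), MSC (-2.80), PANX2 (-2.42), PIR (-2.40), the ferritin heavy chain FTH1 (-2.11), the AP-1 subunit JUN (-2.11), B4GALNT1 (-2.08) and TRIM16L (-1.97), each with an SE of at most 0.21. Reads of TRIM16L can be shared with its near-identical paralog TRIM16, those of FTH1 with processed pseudogenes, and MSC overlaps an antisense gene of similar level (6.22 against 6.16 CPM), so these 3 values are uncertain. The split of calls moved with the scaling: upper-quartile scaling gave 1523 higher and 3052 lower (33.3% higher), and library totals alone 1389 and 3221 (30.1%). Limma on log2(FPKM + 1), where the test, the unit and the genes tested (16789) differ as well, gave 1081 and 2419 (30.9%). Without control replicate 3, the count of lower genes was 1534.

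Targets of NRF2, the transcription factor of the electrophile and oxidant response, were lower as a group. Among the 34 members tested, 26 were lower and 0 higher over all genes tested (29 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -0.67. HMOX1 (hg38 chromosome 22, 35380361 to 35394214) fell from 74.3 ± 20.0 to 1.05 ± 0.32 CPM (SD, n = 3 each), a 70.5-fold difference. The quinone reductase NQO1 fell from 92.2 ± 8.6 to 30.4 ± 0.5 CPM (log2 fold change -1.60, SE 0.08), and the thioredoxin reductase TXNRD1 from 398.9 ± 27.9 to 265.6 ± 8.0 (-0.59, SE 0.06). OSGIN1, PIR and FTH1 had the next largest decreases in the list. FTH1 measured 581.3 ± 74.2 CPM in control and 134.3 ± 2.2 in pristimerin libraries. OSGIN1 overlaps MLYCD on the same strand. Camera called the list lower (adjusted p = 6.5e-16), but not with an inter-gene correlation estimated from the 6 libraries (adjusted p = 0.10 with an estimated correlation).

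Heat shock genes were lower too. Of 32 measured targets of HSF1, the heat shock transcription factor, 21 were lower and 0 higher (22 and 0 adjusted over the list alone), with a median of -0.32. The inducible HSP70 genes HSPA1A and HSPA1B had log2 fold changes of -1.84 (SE 0.10) and -1.67 (SE 0.08), from 147.2 ± 26.5 to 41.0 ± 2.3 and from 109.9 ± 10.3 to 34.5 ± 0.4 CPM (SD, n = 3 each). These genes are near-identical copies, so how reads were divided between them is uncertain. The co-chaperone DNAJB1 fell by 0.44 on the log2 scale, and the collagen chaperone SERPINH1, DNAJB4 and the co-chaperone BAG3 fell by 0.97, 0.80 and 0.72. Camera gave this list an adjusted p of 2.7e-07, and an adjusted p = 0.10 with an estimated correlation. Of 8 measured metallothionein and zinc-response genes, 7 were lower and 0 higher (7 lower and 1 higher adjusted over the list alone; median -0.87). MT2A fell by 1.18, MT1G by 1.13, MT1F by 0.90, MT1E by 0.85, MT1X by 0.72 and the zinc exporter SLC30A1 by 0.49 on the log2 scale. Reads can be shared within the metallothionein family. Camera gave the metallothionein list an adjusted p of 0.00046, and an adjusted p = 0.23 with an estimated correlation.

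Lysosome and autophagy genes regulated by TFEB fell in 23 of 40 cases and rose in 1 (25 and 3 adjusted over the list alone), with a median of -0.33. The lysosomal proteases CTSD and CTSB fell by 1.16 and 0.84, and the autophagy receptor SQSTM1 by 0.58 on the log2 scale. The autophagosome gene MAP1LC3B measured 35.8 ± 3.8 and 36.4 ± 3.1 CPM (SD, n = 3 each; log2 fold change 0.02, SE 0.09), a value whose sign turned under upper-quartile scaling and library totals. Camera gave an adjusted p of 1.8e-05 for the lysosome list, and an adjusted p = 0.076 with an estimated correlation. Of 35 proteasome subunits, 11 were lower and 0 higher, over all genes and adjusted over the list alone, and the median was small (-0.13). PSMB6, ADRM1 and PSMC1 fell by 0.39, 0.34 and 0.32, while PSMA3 (-0.09), PSMB5 (-0.13) and PSMD11 (-0.15) did not pass the test, although PSMB5 did with library totals (-0.20) and PSMD11 with upper-quartile scaling (-0.21), library totals (-0.22), genes above 5 CPM (-0.19), log2(FPKM + 1) (-0.21) and the replicate block (-0.15). Camera gave an adjusted p of 0.006 for proteasome subunits, and an adjusted p = 0.36 with an estimated correlation.

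Among genes listed as restraining ferroptosis, 14 of 34 were lower, 3 higher and 17 not called (15 lower and 3 higher adjusted over the list alone; median -0.20). GPX4, the glutathione peroxidase that reduces lipid hydroperoxides, measured 179.7 ± 14.5 and 185.5 ± 18.7 CPM (SD, n = 3 each), a log2 fold change of 0.05 (SE 0.08) that did not pass the test and changed sign under upper-quartile scaling and library totals. AIFM2, which encodes the coenzyme Q reductase FSP1, fell from 25.1 ± 1.2 to 12.5 ± 2.1 CPM (-1.01, SE 0.11). SLC3A2, the partner subunit of SLC7A11, fell from 356.1 ± 25.3 to 199.7 ± 10.0 CPM (-0.83, SE 0.07). HMOX1 and FTH1 belong to this list as well, and SCD moved the other way (1.82). Whether each listed gene, HMOX1 included, restrains ferroptosis in these cells was not tested. Camera called the list lower (adjusted p = 0.0029), with an adjusted p = 0.25 with an estimated correlation. It shared 11 members with the NRF2 list, and without them 6 of 23 were lower and 3 higher, and camera gave an adjusted p of 0.77; that set was chosen after seeing the data. Of 21 glutathione and cystine supply genes, 9 were lower and 1 higher (11 and 1 adjusted over the list alone; median -0.24), among them SLC7A11, SLC3A2, the glutamate-cysteine ligase subunits GCLM (-1.40, SE 0.08) and GCLC (-0.37, SE 0.07) and PGD (-0.94, SE 0.06). Camera gave an adjusted p of 0.00015 for this list, an adjusted p = 0.21 with an estimated correlation, and 0.18 for the 13 members outside the NRF2 list.

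Genes listed as promoting ferroptosis were higher in 16 of 31 cases and lower in 3, over all genes and adjusted over the list alone (median 0.23). The members with the largest changes were the lipid enzymes FADS2, FADS1 (1.51) and ACACA (1.09), which synthesise or desaturate fatty acids. ACSL4, which activates polyunsaturated fatty acids, rose from 69.2 ± 5.1 to 104.8 ± 11.7 CPM (0.60, SE 0.08), and the transferrin receptor TFRC from 384.8 ± 28.1 to 505.3 ± 17.96 (0.39, SE 0.06). CHAC1, a glutathione-degrading enzyme, was weakly expressed and not called (-0.47, SE 0.34). In camera the drivers had an adjusted p of 0.0018, an adjusted p = 0.10 with an estimated correlation, and 0.13 for the 26 members outside the cholesterol and fatty acid lists. Iron handling genes went both ways, with 9 of 27 higher and 6 lower (10 and 7 adjusted over the list alone). Their median was 0.12 and their mean -0.29, because the decreases were the larger ones: HMOX1, FTH1, the ferritin light chain FTL (-1.19, from 5693 ± 389 to 2502 ± 164 CPM) and the iron exporter SLC40A1 (-0.60). Camera did not call this list (adjusted p = 0.61). Of 42 targets of ATF4 and the integrated stress response, 11 were lower and 5 higher (11 and 7 adjusted over the list alone), and camera did not call the list (adjusted p = 0.12), except lower without control replicate 2 (adjusted p = 0.036) and with cyclic loess normalization (0.0013), the latter chosen after seeing the data, and it was not called with an estimated correlation (adjusted p = 0.68). DDIT3 fell by 0.93 and PPP1R15A by 0.85 on the log2 scale, while TRIB3 (0.01, SE 0.09; its sign turned under upper-quartile scaling and library totals) and ASNS (-0.26, SE 0.27) did not pass the test. DDIT3 overlaps the more highly expressed MARS1 on the opposite strand, and ASNS a more highly expressed long non-coding RNA gene on the same strand.

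Genes of cholesterol synthesis were the most uniformly higher group. Of 24 measured targets of SREBP2, the sterol-regulated transcription factor, 23 were higher and 1 lower, over all genes and adjusted over the list alone, with a median log2 fold change of 1.38. The lower one was PMVK (-0.34, SE 0.09), named after its value was seen. HMGCS1 rose from 86.5 ± 6.4 to 286.0 ± 18.2 CPM (SD, n = 3 each; 3.31-fold). DHCR7 (hg38 chromosome 11) rose from 9.08 ± 0.71 to 58.9 ± 2.5 CPM and MSMO1 from 12.1 ± 1.4 to 58.1 ± 5.7. In camera the adjusted p was 1.8e-21. This was the only list of the 16 called that also passed with an estimated correlation (adjusted p = 0.012 with an estimated correlation). Fatty acid synthesis and desaturation genes were higher in 11 of 18 cases and lower in 3 (12 and 3 adjusted over the list alone; median 0.54). SCD rose from 152.0 ± 5.1 to 536.5 ± 13.6 CPM, FASN from 233.2 ± 33.9 to 565.9 ± 21.9, and the regulator SREBF1 from 30.7 ± 4.8 to 95.5 ± 5.8. FADS1 and FADS2 overlap each other on opposite strands, and FADS2 (129.6 CPM over the 6 libraries) overlaps FEN1 (224.1) on the same strand, so its value is uncertain. Camera gave the fatty acid list an adjusted p of 1.8e-05, and an adjusted p = 0.076 with an estimated correlation.

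**Figure D2:**
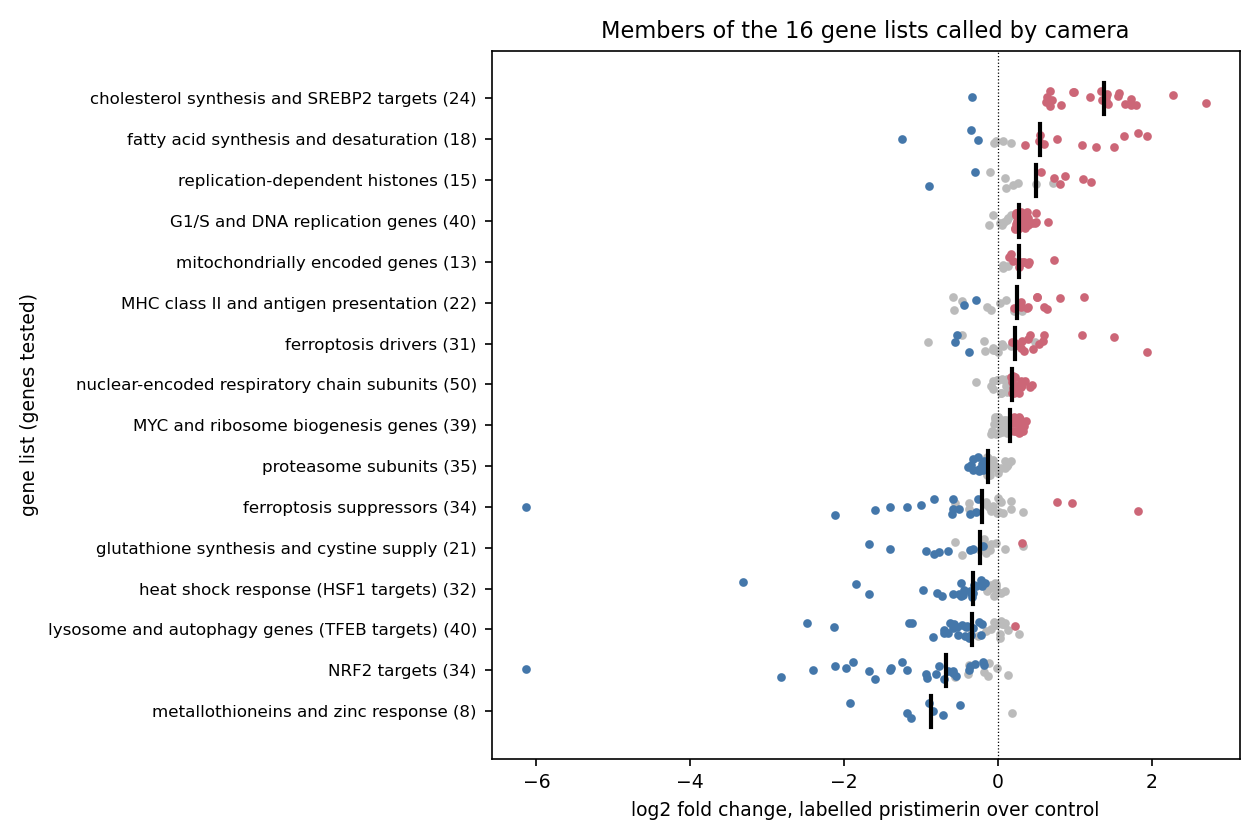
Log2 fold change (labelled pristimerin over control, horizontal axis) of every tested member of the 16 gene lists called by camera, with red and blue points for members called higher and lower, grey points for those not called, and black bars for the list medians; numbers in parentheses count members tested. The cholesterol list has the highest median (1.38) and the metallothionein and NRF2 lists the lowest (-0.87 and -0.67).

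Genes of DNA replication and the G1/S transition were higher by small amounts. Of 40 members, 32 were higher and 0 lower, over all genes and adjusted over the list alone (median 0.28). Examples were the cyclin CCNE2 (0.66, SE 0.08), the ribonucleotide reductase subunit RRM2 (0.48, SE 0.07), the polymerase clamp PCNA (0.34, SE 0.06) and the helicase subunit MCM2 (0.22, SE 0.07). The call of MCM2 was lost under several settings, including upper-quartile scaling and leaving out control replicate 2 (0.15), control replicate 3 (0.23) or pristimerin replicate 1 (0.22) or 3 (0.23). The G1/S list had a camera adjusted p of 8.8e-11, and an adjusted p = 0.18 with an estimated correlation. Of 36 G2/M and mitosis genes, 4 were higher and 3 lower, over all genes and adjusted over the list alone, and the median was 0.03 (camera adjusted p = 0.50). Ribosome biogenesis genes linked to MYC were higher in 18 of 39 cases and lower in 0 (19 and 0 adjusted over the list alone; median 0.16). The nucleolar protein NCL rose from 1553 ± 30 to 1992 ± 9 CPM, GNL3 rose by a log2 fold change of 0.34, and MYC itself measured 332.5 ± 17.1 and 323.8 ± 6.7 CPM (log2 fold change -0.04, not called). NOP56 (0.10) was not called either. The MYC list had a camera adjusted p of 2.6e-05, and an adjusted p = 0.082 with an estimated correlation.

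Respiratory chain genes were modestly higher. Of 50 nuclear-encoded subunits, 24 were higher and 0 lower (28 and 0 adjusted over the list alone; median 0.19), such as COX5A (0.44), SDHD (0.42) and ATP5F1A (0.35). COX4I1 (0.22, SE 0.08) lost its call under several settings, including upper-quartile scaling and leaving out control replicate 1 (0.17) or 2 (0.20) or pristimerin replicate 1 (0.20) or 3 (0.19), and NDUFA9 (-0.29, SE 0.17) was not called. For the nuclear-encoded subunits camera gave an adjusted p of 4.1e-06, and an adjusted p = 0.36 with an estimated correlation. Of the 13 genes encoded by mitochondrial DNA, 10 were higher and 0 lower (11 and 0 adjusted over the list alone; median 0.27). MT-CO3 rose by 0.40, MT-ATP6 by 0.39 and MT-ND1 by 0.28, the last not past the threshold on the log2(FPKM + 1) scale. MT-CO1 (0.07, SE 0.05) was not called, and its value was -0.0002 with library totals alone. For mitochondrially encoded genes it was 0.00024 in camera, and an adjusted p = 0.37 with an estimated correlation. The call was also lost (adjusted p = 0.11) with cyclic loess normalization, which removes a trend of fold change with abundance and was chosen after seeing the data.

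Antigen presentation genes were higher in 11 of 22 cases and lower in 2, over all genes and adjusted over the list alone (median 0.25). The members that moved most encode MHC class I molecules: HLA-B rose from 181.1 ± 11.4 to 392.3 ± 24.3 CPM (1.12, SE 0.07), HLA-C by 0.81 and HLA-E by 0.64. Among the class II genes of the list, CD74 rose (0.29, SE 0.07), HLA-DRA was not called (0.21, SE 0.11), and the class II activator CIITA was lower (-0.45, SE 0.13), a call lost on log2(FPKM + 1) (-0.13) and without control replicate 3 (-0.31) or pristimerin replicate 3 (-0.40). HLA genes are polymorphic and similar in sequence, so their counts are uncertain. Camera gave an adjusted p of 0.0094 for antigen presentation, and an adjusted p = 0.57 with an estimated correlation. Replication-dependent histone genes were higher in 6 of 15 cases and lower in 2, over all genes and adjusted over the list alone (median 0.50). H2BC12 rose by 1.11, H2BC21 by 0.80 and H1-2 by 0.57. Most histone transcripts lack a poly(A) tail and are caught only in part by poly(A) selection. Histones had a camera adjusted p of 0.0091, and an adjusted p = 0.27 with an estimated correlation.

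Interferon-stimulated genes divided, with 9 of 34 higher and 10 lower (10 and 10 adjusted over the list alone). BST2 fell from 181.4 ± 9.3 to 101.9 ± 5.4 CPM (SD, n = 3 each), HERC5 by 1.05 and SAMD9L by 0.69 on the log2 scale. IFIT1 was higher from a low level, 1, 4 and 3 counts in the control and 23, 32 and 35 in the pristimerin libraries, and it overlaps LIPA on the opposite strand. ISG15 (-0.06) and MX1 (0.44) were not called. The list's median was -0.01 and its mean 0.27, and camera did not call it (adjusted p = 0.77). Of 25 NF-kappaB and inflammatory cytokine genes, 8 were higher and 4 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.068). TNFAIP3 rose from 4.80 ± 0.40 to 17.6 ± 2.0 CPM, IRF1 by 0.95 and RELB by 0.89 on the log2 scale. NFKBIA (0.21, SE 0.07) lost its call with upper-quartile scaling (0.15), library totals (0.14) and log2(FPKM + 1) (0.13), and without control replicate 1 (0.20) or 3 (0.23) or pristimerin replicate 1 (0.21) or 3 (0.22), and CXCL8 (0.22, SE 0.17) was not called. Camera called this list higher with upper-quartile scaling (adjusted p = 0.031), library totals (0.026) and no low-count filter (0.00015), without control replicate 1 (0.012), and with cyclic loess normalization, chosen after seeing the data (0.023), but not with an estimated correlation (adjusted p = 0.23).

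Camera did not call the remaining lists. The counts higher and lower were 6 and 5 of 34 for the endoplasmic reticulum unfolded protein response, 6 and 5 of 28 for immediate early and AP-1 genes, 3 and 3 of 27 for p53 targets, 7 and 1 of 31 for the BCL2 family, 0 and 3 of 58 for cytosolic ribosomal proteins, 7 and 4 of 27 for glycolysis and hypoxia genes, 6 and 8 of 26 for monocyte and macrophage differentiation genes, and 5 and 6 of 27 for genes of MLL-rearranged leukaemia and progenitors. Adjusted over the list alone, these counts were the same except for ribosomal proteins (0 and 1), glycolysis (7 and 5) and monocyte genes (8 and 8). The BCL2 family was called higher with no low-count filter (camera adjusted p = 0.032), and ribosomal proteins lower with cyclic loess normalization, chosen after seeing the data (2.1e-06); neither was called in the main setting with an estimated correlation (adjusted p = 0.27 and 0.96). Camera's direction had the opposite sign of the median and the mean for the unfolded protein response (up; -0.04 and -0.01), monocyte genes (down; 0.01 and 0.01) and leukaemia and progenitor genes (up; -0.02 and -0.05), while AP-1 genes had a median of 0.02 and a mean of -0.08 and lymphoid markers 0.06 and -0.20. Few of the listed markers of cell types other than monocytic cells passed the low-count filter. Of 18 lymphoid markers 5 were measured, with 1 higher and 2 lower over all genes and adjusted over the list alone (camera adjusted p = 0.92). The 11 lymphoid markers in the count table, mostly CD4 (mean 161.5 CPM), summed to 187.4 ± 6.4 and 178.4 ± 5.6 CPM (SD, n = 3 each). The marker sums are not scaled by TMM, so small differences between the groups are not read from them. The erythroid and megakaryocyte markers summed to 35.5 ± 2.2 and 30.5 ± 2.2 CPM and the epithelial and fibroblast markers to 24.1 ± 3.8 and 16.4 ± 1.1, and with fewer than 5 measured members neither list was tested.

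Long non-coding RNA genes took 1.78% ± 0.03 (SD, n = 3) of the counts in control and 1.57% ± 0.01 (SD, n = 3) in pristimerin libraries, and the 13 mitochondrial genes 4.79% ± 0.20 and 5.25% ± 0.13. The libraries of the groups did not overlap in either share, and the exact two-sided permutation test gave p = 0.1 for both, the smallest value that 3 against 3 libraries allow. Relative to the plain library totals, not scaled by TMM, the abundant nuclear RNA NEAT1 measured 471.1 CPM in control and 204.0 in pristimerin libraries. SNHG32 measured 194.5 and 95.2, and GAS5, a host gene of small nucleolar RNAs, 229.2 and 143.5. With TMM, their fitted log2 fold changes were -1.14, -0.96 and -0.60. These 3 genes were named after their values were seen. Fold changes also depended on abundance. The median log2 fold change of protein-coding genes was -0.23 at a mean of 0.1 to 1 CPM (977 genes), -0.15 at 1 to 10 CPM (2665 genes), 0.02 at 10 to 100 CPM (6575 genes) and 0.11 above 100 CPM (2287 genes). Among genes with a mean of at least 5 CPM, 63 were at least 2-fold higher and 66 at least 2-fold lower.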

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

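Cyclic loess normalization, lists without shared members, every alternative of the replicate agreement, and log2(FPKM + 0.1) and protein-coding genes alone for ATF3 and SLC7A11 were chosen after seeing the data. SLC7A11 and ATF3 stayed lower and past the threshold wherever tested, with log2 fold changes of -1.75 to -0.81 and -2.69 to -0.47; ATF3 is too low for the 5 CPM filter. Of 96 called named genes, 89 kept direction and call under the alternatives planned for named genes. Further settings were run on the other named genes and are left out of that count, a choice made after seeing the data: 5 of 110 changed sign with cyclic loess, none of them called in both settings, with values up to 0.2642 from 0, and 5 lost and 3 gained a call; log2(FPKM + 0.1) changed the sign of 3 of 109, with 7 calls lost and 1 gained, and protein-coding genes alone changed 2 of 109, with 1 lost and 1 gained. In the planned settings the calls lost were 36 gene and setting pairs, and 6 pairs gained one.

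The count of higher genes fell from 2216 to 1389 with library totals, 1081 on log2(FPKM + 1) and 1084 on log2(FPKM + 0.1). The 2-fold counts, 139 higher and 391 lower, became 63 and 66 above 5 CPM, 47 and 40 on log2(FPKM + 1), 110 and 322 on log2(FPKM + 0.1), and 231 and 196 with cyclic loess; protein-coding genes alone had 256 lower. The 5 CPM filter and the protein-coding restriction test fewer genes and the pseudocount shrinks folds of low genes. Library totals moved the median log2 fold change of all genes from -0.0129 to -0.0842. Otherwise the cause was not tested. Leaving out 1 library gave 1742 to 2357 higher and 1534 to 2329 lower, with the lowest counts without control replicate 3. No gene called in both settings changed sign under any alternative. Against 9 lists higher and 7 lower, camera with an estimated correlation called 1 and 0 (5 and 3 at an unadjusted p under 0.05), and fry, a different question, called 12 and 11; leaving out 1 library gave 9 to 10 and 7 to 8. Fry called iron handling lower (list median 0.1187) where camera's direction was up.

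Uncalled values near 0 changed sign. GPX4 was -0.0126 with upper-quartile scaling, -0.0243 with library totals, -0.0268 on log2(FPKM + 1) and -0.0137 (without control replicate 2) to 0.13 when 1 library was left out. TRIB3 was -0.0467, -0.0577 and -0.0523 in the first 3 of these, -0.021 above 5 CPM, and -0.096 (without control replicate 2) to 0.0876 with 1 library left out, also negative without pristimerin replicate 1 (-0.0469). MAP1LC3B was -0.0394, -0.0504, -0.04 and -0.0133 in those first 4, and -0.0473 (without pristimerin replicate 2) to 0.1147 with 1 library left out, also negative without control replicate 1 (-0.0345). MT-CO1 was -0.0002 with library totals, and ISG15 lay between -0.1457 and 0.0633 (without control replicate 3) with 1 library left out. Upper-quartile scaling and library totals lowered all genes nearly alike, and values near 0 turned negative there. The median log2 fold change of all genes moved from -0.0129 to -0.0728 and -0.0842. The cause in the other settings was not tested.

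Deviations of same-numbered libraries from their group means correlated across genes at 0.098, 0.137 and 0.037 (mean 0.0905, and 0.0271 with no filter), so not every pair exceeded 0.1 and the numbers are not taken to pair the libraries, although each library correlated best with its own number. A factor shared by same-numbered libraries is therefore not excluded. With the replicate block, 3150 genes were higher and 2948 lower, 137 and 411 at least 2-fold, with the same 9 and 7 lists. Depth limits ATF3, with 5 to 57 counts per library, and genes under 1 CPM.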

Other observations

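The test of exchanged labels was chosen after the direction of the stress genes was seen, the test of the long non-coding RNA share by level after the shares were seen, and the pathway sets were chosen after seeing the data; the other tests of this part were written down before the values they measure were computed. Pathway sets taken from the annotation column of the deposited tables added some gene groups, repeated some calls of the fixed lists and did not repeat others. Of 322 pathways with 10 to 300 genes, camera called 80 higher and 4 lower, and 0 with an estimated correlation (57 at an unadjusted p under 0.05), so these are descriptions only. Camera compares a set with all other genes tested, whose fold changes depended on abundance. Of 2287 protein-coding genes above 100 CPM, 811 were higher and 183 lower. Neither these sets nor the fixed lists were matched for abundance. Among the citrate cycle genes, 19 of 28 were higher and 0 lower (median log2 fold change 0.24; camera adjusted p = 2.6e-05, adjusted p = 0.27 with an estimated correlation). Among genes of nucleocytoplasmic transport, 38 of 101 were higher and 4 lower (camera adjusted p = 4.1e-05, adjusted p = 0.30 with an estimated correlation). Among genes of other glycan degradation, a lysosomal group, 0 of 16 were higher and 12 lower (median -0.33; camera adjusted p = 0.0003, adjusted p = 0.25 with an estimated correlation). Camera called steroid biosynthesis (16 higher and 0 lower of 18, adjusted p = 9.3e-10), lysosome (10 and 54 of 119, 8.7e-05) and DNA replication (20 and 2 of 35, 0.00012) like the fixed lists. So it did ribosome biogenesis (25 and 4 of 73, 0.00033) and oxidative phosphorylation (46 and 4 of 121, 0.0004). None of these passed with an estimated correlation (adjusted p from 0.25 to 0.45). Not called by camera were ferroptosis (10 higher and 10 lower of 37; adjusted p = 0.73), glutathione metabolism (10 and 14 of 41; 0.26), proteasome (5 and 10 of 43; 0.28), antigen processing and presentation (13 and 11 of 48; 0.98), fatty acid biosynthesis (4 and 3 of 14; 0.44) and fatty acid metabolism (16 and 10 of 49; 0.14). Nor did camera call the 2 autophagy sets (17 higher and 18 lower of 120; adjusted p = 0.91, and 1 and 1 of 31; 0.92). The fall of the fixed lysosome and autophagy list was thus repeated by the lysosome set and not by the autophagy sets.

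In 10 splits of the 6 libraries into 3 and 3, the labelled split, with 4529 genes called, was the only 1 of the 10 to reach that number, and the highest of the other splits called 0 by edgeR and 0 by limma-voom at an adjusted p under 0.05, with 107 to 566 genes at an unadjusted p under 0.05 in edgeR. With 10 splits no share under 0.05 can be reached. Each of the other splits also mixes libraries of both labels on each side. The difference between the labels then adds to the spread within each side, which lowers the number of calls. The 0 calls therefore do not show how many genes a division unrelated to the labels would call. No conclusion is drawn from the contrast with 4529.

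Genes of the NRF2, heat shock and metallothionein lists were lower in the libraries labelled pristimerin, with 0 members higher in each over all genes tested; camera called these lists lower, but not with an estimated correlation (adjusted p = 0.10, 0.10 and 0.23). The integrated stress response list was not called (adjusted p = 0.12; 11 lower and 5 higher of 42). As background, quinone methides react with thiols, and such compounds usually raise NRF2 and heat shock targets. Under the other 3 scalings the medians nearest to 0 were -0.66 for the NRF2 list and -0.31 for the heat shock list. These scalings shift all genes nearly alike, with a median log2 fold change of all genes between -0.0842 and -0.0026. They could not bring either list near 0, so only the choice among them was examined, and a larger scaling error was not tested. A single aberrant library is argued against, since leaving out each in turn kept the NRF2 median at -0.62 or below. An exchange of the group labels would mirror every value, and the 63 members called lower of 114 in these 4 lists together would then be higher. An exchange and a true decrease therefore cannot be told apart from these values. The sample titles do not name the treatment. In the group labelled pristimerin they hold the cell line name and a number, and in the group labelled control a letter and a number. This naming does not decide the question, and no sample outside these groups was analysed here. Exposure time stays open as well and was not tested, so whether the direction may reflect the labels or the biology of the treatment is a question for the submitters' records.

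Sterol synthesis genes were higher in the libraries labelled pristimerin (median 1.38). Under the other 3 scalings the median nearest to 0 was 1.31. These scalings shift all genes too little to bring it near 0, so a larger scaling error was not tested. One hypothesis, a lower sterol content of the cells, was taken to predict lower targets of the sterol-sensing receptor LXR. Of 8 targets tested, out of 9 fixed for this purpose, 6 were higher and 1 lower (median log2 fold change 0.72). ABCA1 was at 1.06 and MYLIP at 1.33, and the lower one was NR1H3 (-0.48), all named after their values were seen. The predicted fall was not seen. Sterol content itself was not measured and LXR targets read it only indirectly, so the hypothesis is not excluded. What raised both groups stays open, the exchange of labels included, and was not tested.

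Long non-coding RNA genes took a smaller share of counts in the libraries labelled pristimerin. A few abundant genes are argued against as the whole cause, since without the 10 genes that contributed most the log2 ratio of the shares was still -0.13, against -0.18 for all. A lower level of all weakly expressed genes is argued against as the whole cause too, since 52.9% of the fall in share came from the 310 long non-coding RNA genes with a mean over 10 CPM, against 14.2% from genes under 1 CPM and 32.9% from genes at 1 to 10 CPM. Most of that 52.9% is the same 10 genes (41.9%), and the other 300 add 11.1%, so the 10 genes and the weakly expressed ones together cover most of the fall and neither test excludes their combination. Weakly expressed genes may account for a part: at a mean of 0.1 to 1 CPM the median log2 fold change was -0.23 for protein-coding genes and -0.26 for long non-coding RNA genes, and at 1 to 10 CPM -0.15 and -0.18, while at 10 to 100 CPM it was 0.02 and -0.05. Why these genes were lower, whether through RNA composition, library preparation or the treatment, was not tested.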
